A study of Homo sapiens with 6 samples.

How the data were processed

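Messenger RNA libraries were made with a stranded kit and sequenced on an Illumina instrument, per the labels' protocols, from human macrophages derived from blood monocytes of healthy volunteers. The labels put 3 libraries in the control group and 3 in the TSN group and number the replicates 1 to 3 in each. They describe culture in tumor endothelial cell medium with TSN. They do not describe the control's vehicle or say whether the controls received that medium.

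The authors deposited a single table of normalized signal, a per-gene CPM already filtered and scaled. Per the submitters' processing notes, kallisto 0.45.1, edgeR 3.14.0 and the build GRCh38 were used, with no settings given. The deposited signal columns sum to between 944428 and 1238200, so they are not shares of a plain total, as a scaled library size as divisor would give; the sources used here do not state it. The table lists 26074 genes, 1837 of them at 0 in all 6 libraries, and 24 entries whose names read as dates, with 2 such names on more than 1 row, were left as they stand. A value of 0 may be a failed estimate, because genes averaging at least 100 CPM elsewhere were listed at 0 in every library (1 to 5 genes per library).

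Depth was estimated from the most frequent low value in each library, taken as 1 read. Of the values up to 20 reads, 25.5%, 23.8% and 16.6% in control replicates 1 to 3 and 30.0%, 13.5% and 6.25% in TSN replicates 1 to 3 were whole multiples of it within 0.01 read. Most values were fractions of a read, so whole reads were not recovered and the planned tests on read counts were not run. A floor of 3 reads corresponds to 0.501, 0.767 and 1.91 CPM in the controls and 0.473, 1.60 and 4.90 CPM in the TSN libraries. TSN replicate 3, with 719514 reads, gives the least precise values. Depth in the control exceeded that in the TSN library 1.66-fold in replicate 2 and 2.34-fold in replicate 3, and the ratio was 0.946 in replicate 1.

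Values were transformed as log2(CPM + 1). The 12747 genes with at least 1 CPM in at least 3 libraries, 48.9% of the table, were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The main fit, chosen before the data were examined, had the group alone; a fit with the replicate number as a block was chosen in advance as the other fit. Whether the numbers pair the libraries was decided from the correlation, across genes, of same-numbered libraries' deviations from their group means. These were 0.81, 0.36 and 0.56 for replicates 1, 2 and 3, all above 0.1. Among the libraries of the other group, 5 of the 6 libraries were closest in these deviations to the one with their own number, but over all libraries the log2 values of only 2, those of replicate 1, correlated best with their own number. The numbers were therefore read as pairs, and the pairing comes from the numbers in the labels and this check, since no label states a shared donor or day. In both groups depth fell and mitochondrial share rose from replicate 1 to 3. Such a gradient could also make same-numbered deviations correlate, so the check cannot establish a shared donor or day.

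A set of 39 gene lists was fixed before the data were examined and tested with camera at a preset correlation of 0.01, and, as alternatives, with an estimated correlation and with fry; lists with fewer than 5 genes tested got no test. Each list's median was also set against 10000 random lists of the same size matched on mean expression. Gene symbols that differ from the table were matched through older names. Coordinates come from GENCODE 29 on GRCh38.

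Genes were named by a rule fixed in advance. It took the 10 largest increases and decreases past the threshold with non-overlapping groups and at least 5 CPM, up to 4 passing members of each list, or up to 2 further members of highest mean where fewer than 2 passed, and 8 markers and kinases in any case. Genes whose level depends on a donor's sex or on common germline variants were left out. Because the main fit called 0 genes, the same rule was applied to the paired fit, with the same direction in every pair in place of non-overlap; this was decided after the main fit was seen. Some genes that the rule takes are not reported here. Genes named outside the rule are identified where they appear.

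The fits were tested on simulated data. In simulated pairs of these libraries (12284 genes), the paired fit recovered 1.47% of genes changed 2-fold, 15.2% of those changed 4-fold and 54.5% of those changed 16-fold, with 0 false calls; without the block these were 0, 0 and 10.6%. Camera called 2 of 2 moved lists and 0 of 10 unmoved lists. The simulated noise was independent between genes and the lists were random genes, so false calls for lists of correlated genes were not tested. The simulated libraries were built from the means of same-numbered libraries and the spread left by the paired fit. Pairs were therefore built in, and the gain from the block and the 0 false calls do not show that the replicate numbers are true pairs. Alternatives covered the pseudocount (0.1 and 5), the filter (none and 5 CPM), quantile normalization, median centring, the trend, robust estimation, library weights and leaving out each library. Combining these with the block, leaving out whole pairs, weighting by precision, a correction for transcript length and GC content and thinning to equal depth, all with the block, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.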

Results

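RNA was sequenced from human macrophages grown from blood monocytes with 10 ng/ml CSF-1 for 3 days. For treatment, the labels describe 1 day in medium conditioned by endothelial cells from human glioblastoma with toosendanin (TSN). TSN, a triterpenoid of the Melia tree, was present at 50 nM in 3 libraries, and 3 libraries were controls. The labels do not give the controls' vehicle or say whether the controls received the conditioned medium. If they did not, an effect of TSN cannot be told apart from one of the medium. Estimated depth was 5663716, 3850030 and 1684720 reads in control replicates 1, 2 and 3, and 5984659, 2324311 and 719514 in TSN replicates 1, 2 and 3, an 8.32-fold range. Mitochondrial transcripts took 5.37%, 8.76% and 13.03% of the signal in the controls and 6.03%, 20.1% and 20.3% in the TSN libraries, in the same order. The widest Wilson 95% interval of these shares was 0.186 percentage points, and such intervals cover counting error only. The labels do not say whether replicates were separate donors or cultures, so p-values measure only the spread between these samples, which may be technical.

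The first question was how closely libraries of one group agreed. Across genes, the Pearson correlation of log2 values between controls ran from 0.74 (replicates 1 and 3) to 0.89 (replicates 2 and 3), and between TSN libraries from 0.65 (replicates 1 and 3) to 0.93 (replicates 2 and 3); genes are not independent replicates. The TSN and control libraries of replicate 1 correlated at 0.95, above any pair within a group. The first principal component, with 64.7% of the variance, had both libraries of replicate 1 at one end. Control replicates 1 to 3 lay at −111, −4.88 and 49.3 on it, and TSN replicates 1 to 3 at −109, 75.9 and 99.9. The 6 libraries thus lay along it in the order of their mitochondrial share, with control replicate 2 between the ends. ACTB, the cytoskeletal actin gene, was chosen after its values were seen as an example of this spread: it read 484, 3892 and 10306 CPM in control replicates 1 to 3 and 122, 6532 and 5096 CPM in the TSN libraries.

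**Figure D1:**
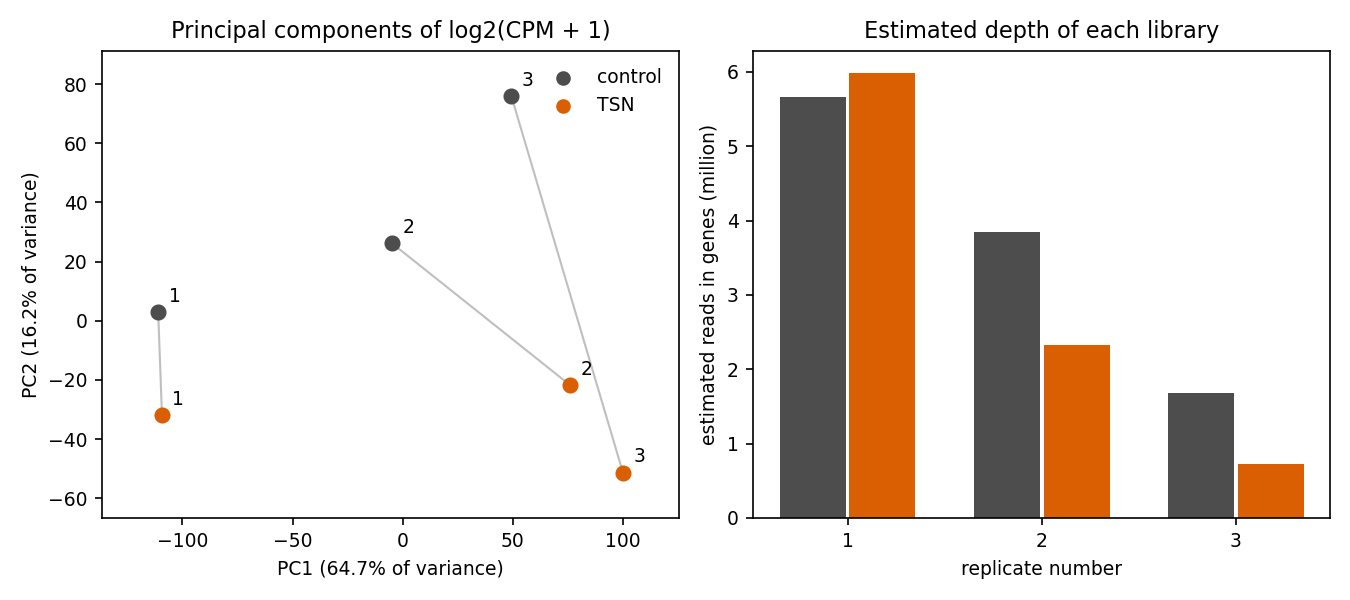
Left, principal components 1 and 2 of log2(CPM + 1) for the 6 libraries, with points numbered by replicate and lines joining libraries of the same number. Component 1 (64.7% of variance) has replicate 1 at one end and orders the libraries by mitochondrial share. Right, bars of estimated reads in genes per library, from 719514 in TSN replicate 3 to 5984659 in TSN replicate 1.

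The main comparison asked which genes differed between macrophages with and without TSN. With the replicate number as a block, TSN macrophages had 109 genes higher and 118 lower of 12747 tested. Each of these 227 moved the same way in all 3 pairs, with a mean change over the pairs of at least 2-fold. The paired test favours such genes, and 37.2% of all genes tested moved the same way in all 3 pairs (25% expected by chance). TSN and control values did not overlap for 152 of the 227, and for 8.94% of all genes (10% expected by chance). SCD, the stearoyl-CoA desaturase, rose 10.3-fold, from 219 ± 41.2 to 2478 ± 1459.8 CPM (SD, n = 3; log2 3.36, SE 0.35, limma adjusted p = 0.00302). MS4A6A, a membrane protein gene of monocytes and macrophages, fell 16.2-fold, from 288 ± 117 to 17.7 ± 8.90 CPM (log2 −4.02, SE 0.37, adjusted p = 0.00206). The fit planned before the data were examined had no block and called 0 genes with limma, against 547 at an unadjusted p under 0.05 where 637 were expected by chance; its smallest adjusted p was 0.687. Library weights, which did not converge, gave 4607 genes in that fit. The paired count was 456 without replicate 1, 146 without replicate 2 and 36 without replicate 3, which holds the shallowest library. It was 0 when no mean-variance trend was fitted, when no low-value filter was used, or when all libraries were thinned to equal depth. Except where stated, rose and fell refer below to this paired fit, with fold changes on the log2(CPM + 1) scale. All of its calls rest on reading the replicate numbers as pairs, which no label states.

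The 10 largest increases among genes averaging at least 5 CPM included those of FZD4, PTGES, SLC2A5, ENO2, FADS2, SCD, WDR54, SULF2 and ZMIZ1-AS1, with log2 changes from 3.34 to 4.19. ENO2, a glycolytic enolase, rose from 10.9 ± 6.31 to 142 ± 56.2 CPM (n = 3; log2 3.64, SE 0.43, adjusted p = 0.00425). SULF2, an extracellular heparan sulfatase, rose from 37.8 ± 27.1 to 455 ± 311 CPM (log2 3.35, SE 0.36, adjusted p = 0.00316). SLC2A5, the fructose transporter, read 14.2, 0.81 and 0 CPM in control replicates 1 to 3 and 84.0, 27.9 and 29.6 CPM with TSN; its log2 change was 3.80, but 5.24 with a pseudocount of 0.1 and 2.50 with 5. ZMIZ1-AS1 is antisense to its neighbour, and without a stated strand setting its reads cannot be assigned with certainty. Without replicate 3, PTGES (log2 2.58, adjusted p = 0.0712) and WDR54 (2.73, adjusted p = 0.106) no longer passed, and without replicate 2 WDR54 did not either (3.24, adjusted p = 0.0876).

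The 10 largest decreases were in CD163L1, MS4A6A, GIMAP6, PDK4, ENC1, CCL24, POLR1D, IL2RA, CD38 and TGFBI, with log2 changes from −4.46 to −3.25. TGFBI, a secreted matrix protein, fell from 886 ± 382 to 126 ± 93.7 CPM (n = 3; log2 −3.25, SE 0.40, adjusted p = 0.00446). PDK4, an inhibitory kinase of pyruvate dehydrogenase, fell from 302 ± 459 to 26.7 ± 43.1 CPM (log2 −3.53, SE 0.36, adjusted p = 0.00284). ENC1 fell from 66.2 ± 39.1 to 4.28 ± 0.225 CPM (log2 −3.51, SE 0.43, adjusted p = 0.00441). CD163L1 overlaps CD163 in the annotation, so reads may be split between them. CD163L1 (log2 −2.58, adjusted p = 0.104) and POLR1D (−2.45, adjusted p = 0.104) did not pass without replicate 3, nor did CCL24 without replicate 2 (−3.39, adjusted p = 0.133). Without replicate 1, SLC2A5, CCL24, IL2RA and CD38 were below the filter and not tested. Of these decreases, GIMAP6, CCL24, POLR1D, IL2RA and CD38 moved by over 1.5 times with the pseudocount: IL2RA had a log2 change of −3.32, but −5.58 with 0.1 and −1.81 with 5, and CD38 of −3.30, −5.46 and −1.96, so the ranking depends on it.

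**Figure D2:**
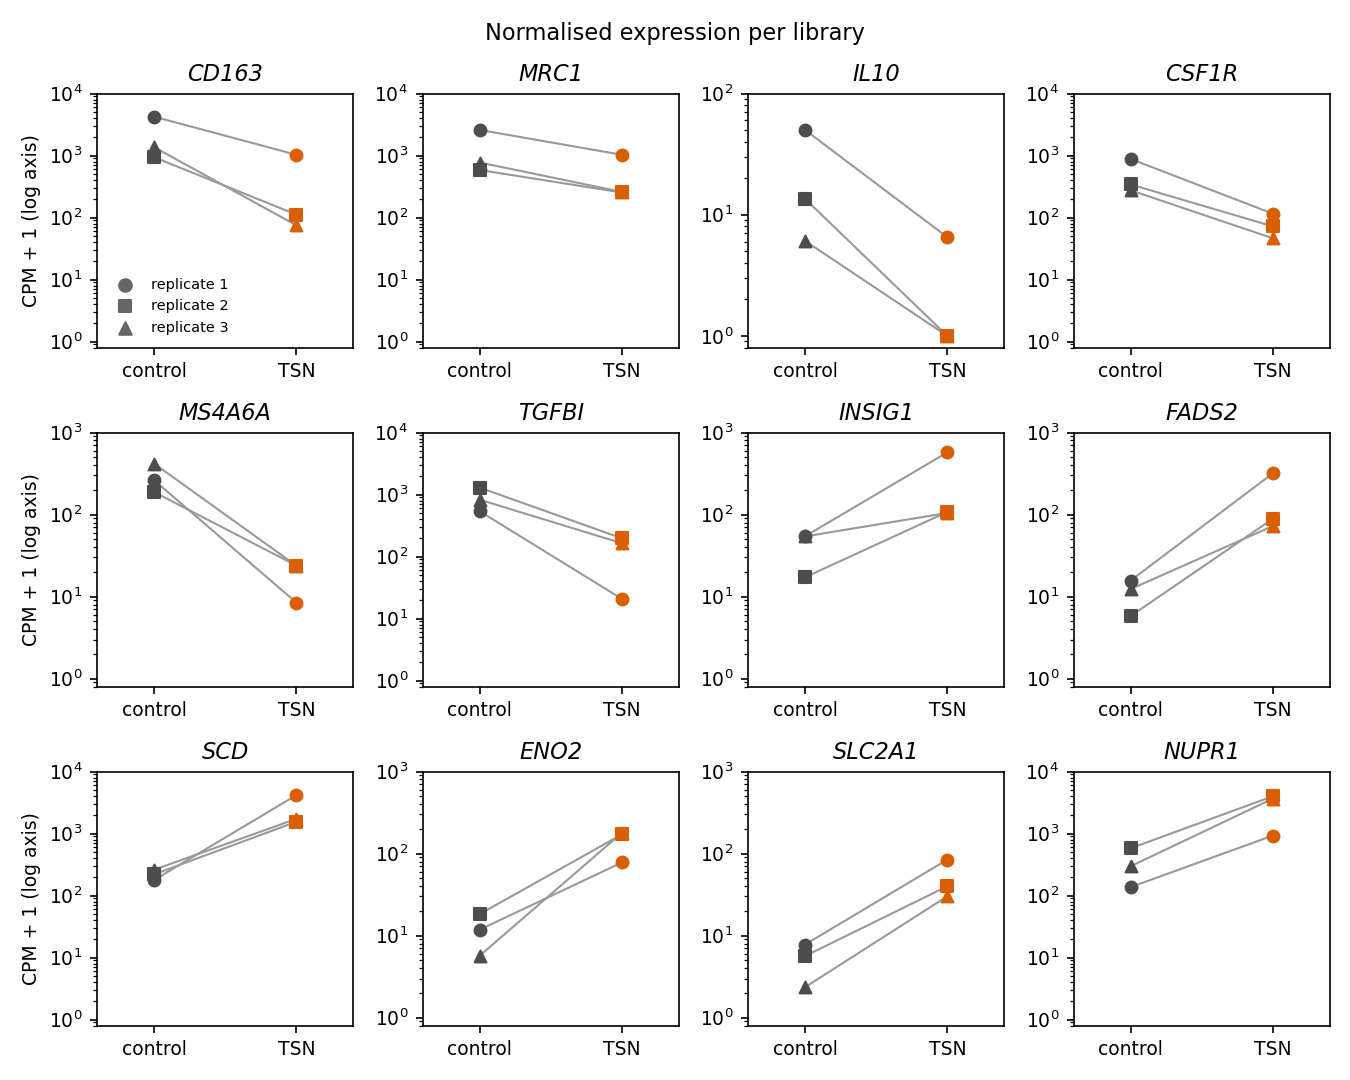
Normalised expression (CPM + 1, log axis) of 12 genes in each of the 6 libraries, with control in grey, TSN in orange, marker shapes for replicates 1 to 3 and lines joining libraries of the same number. CD163, MRC1, IL10, CSF1R, MS4A6A and TGFBI are lower and INSIG1, FADS2, SCD, ENO2, SLC2A1 and NUPR1 higher with TSN in all 3 pairs.

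Markers of alternatively activated and tumor-associated macrophages, and kinases, were compared next, because work on this compound concerns immunosuppressive macrophages in glioblastoma. CD163, the hemoglobin scavenger receptor, fell 8.58-fold, from 2178 ± 1791 to 404 ± 540 CPM (n = 3; log2 −3.10, SE 0.36, adjusted p = 0.00425). CSF1R, the receptor for the growth factor used to make these cells, fell from 499 ± 333 to 77.0 ± 34.9 CPM (log2 −2.58, SE 0.25, adjusted p = 0.00284). MRC1, the mannose receptor, fell from 1314 ± 1107 to 513 ± 446 CPM (log2 −1.37, SE 0.24, adjusted p = 0.0230). IL10, an anti-inflammatory cytokine, fell (log2 −3.10, SE 0.52, adjusted p = 0.0177); it read 49.0, 12.5 and 5.08 CPM in the controls and 5.52 CPM in TSN replicate 1, and was listed at 0 in TSN replicates 2 and 3. The log2 change of IL10 was −5.27 with a pseudocount of 0.1 and −1.73 with 5. None of these 4 passed without the block. MRC1 did not pass without replicate 3 (log2 −1.27, adjusted p = 0.327), IL10 did not pass without replicate 2 (−2.77, adjusted p = 0.0896) and was below the filter without replicate 1.

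Other markers fixed in advance did not pass. ABL1, a tyrosine kinase, was 60.5 ± 36.1 CPM in controls and 22.8 ± 24.9 CPM with TSN (n = 3; log2 −1.77, SE 0.39, adjusted p = 0.0537), and passed only without replicate 1 (−2.16, adjusted p = 0.0342) among the fits that left out a pair; it passed in 7 of 14 paired settings in all. TGFB1 was 167 ± 54.3 CPM in controls and 234 ± 76.4 CPM with TSN (log2 0.49, SE 0.24, adjusted p = 0.340). ARG1, encoding arginase 1, was below the filter: it read 0.361, 0.129 and 0 CPM in the controls and 0.865, 0 and 0 CPM with TSN. The floor of 3 reads lay between 0.473 and 4.90 CPM per library, so a difference was not detectable at this depth.

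In the GENCODE 29 annotation of GRCh38, CD163 lies on chromosome 12 from 7470813 to 7503893, CSF1R on chromosome 5 from 150053291 to 150113372, MRC1 on chromosome 10 from 17809344 to 17911170 and IL10 on chromosome 1 from 206767602 to 206772494. SCD lies on chromosome 10 from 100347124 to 100364834, ENO2 on chromosome 12 from 6913745 to 6923698 and MS4A6A on chromosome 11 from 60172014 to 60184666. All 7 are protein-coding, and each value is a sum over the gene.

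Gene lists fixed before the data were examined were then tested as groups. Of 34 lists with at least 5 genes, camera with a preset correlation called 10 without the block (5 higher, 5 lower) and 9 with it. With an estimated correlation it called 0 in either fit, where 6 lists had an unadjusted p under 0.05 without the block and 1 with it. With the block, the estimate was −0.0073 for glycolysis, −0.0127 for monocyte markers and −0.0155 for MHC class II, below the preset 0.01. It was 0.0155 to 0.850 for the other lists called. Losing a call with an estimated correlation is therefore not by itself a sign of correlated genes. The estimated form also takes its degrees of freedom from the 6 libraries and not from the genes, so it has little power here. Its smallest adjusted p over all lists was 0.166 without the block and 0.498 with it. A call lost in this way is thus weak evidence against a list. The test fry, which asks whether a list's genes move on balance in one direction, also called 0 in either fit, with smallest adjusted p of 0.0540 and 0.0903. Unadjusted, its p was under 0.05 for 5 lists without the block and 7 with it. In its mixed form, which disregards direction, fry called 4 lists without the block and 19 with it.

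Cholesterol synthesis genes were higher with TSN. Of 24 genes of sterol synthesis and uptake, 11 rose, 0 fell and 13 did not pass; adjusted over the list alone, 20 rose. INSIG1, a sterol sensor, rose from 40.9 ± 21.4 to 261 ± 270 CPM (n = 3; log2 2.33, adjusted p = 0.0215). MSMO1, a sterol methyl oxidase, rose from 12.6 ± 7.78 to 66.1 ± 35.1 CPM (log2 2.32, adjusted p = 0.0411). The list's median difference was 1.57, against −0.36 to 0.18 for random lists, and 1.98, 1.68 and 0.93 in replicates 1, 2 and 3. The camera call (adjusted p = 3.58e-21 without the block, 6.31e-17 with it) was lost with an estimated correlation (adjusted p = 0.166 without the block, 0.498 with it). Of the 11 genes, 8, 6 and 5 passed without replicate 1, 2 and 3. INSIG1 did not pass without replicate 2 (log2 2.17, adjusted p = 0.0587), nor MSMO1 without replicate 1 (1.75, adjusted p = 0.0765) or 2 (2.14, adjusted p = 0.125).

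Genes of glycolysis and the hypoxia response were also higher. Of 36 tested, 11 rose, 2 fell and 23 did not pass, with 22 and 2 adjusted over the list alone. The glucose transporter genes SLC2A1 and SLC2A3 rose from 4.26 ± 2.74 to 50.6 ± 28.9 CPM (n = 3; log2 3.32, SE 0.41, adjusted p = 0.00509) and from 92.8 ± 46.7 to 590.4 ± 227 CPM (log2 2.69, SE 0.28, adjusted p = 0.00284). NDRG1, a hypoxia-responsive gene, rose from 94.5 ± 34.2 to 536 ± 91.1 CPM (log2 2.55, SE 0.26, adjusted p = 0.00284). HIF1A, a subunit of the hypoxia-inducible factor itself, fell (log2 −1.59, SE 0.26, adjusted p = 0.0176), as did the hexokinase gene HK3 (−1.31, SE 0.27, adjusted p = 0.0439), named after its values were seen. HK3 passed in 7 of 14 paired settings. It did not pass without replicate 1 (−1.24, adjusted p = 0.0569), 2 (−1.29, adjusted p = 0.158) or 3 (−1.38, adjusted p = 0.288). The list's median was 0.87, against −0.25 to 0.20 for random lists. The camera call (adjusted p = 6.99e-14 without the block, 6.43e-11 with it) was lost with an estimated correlation (adjusted p = 0.166 and 0.498). Of these 13 genes, 10, 10 and 4 passed without replicate 1, 2 and 3; the 4 were ENO2, SLC2A1, SLC2A3 and NDRG1.

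Targets of the integrated stress response, the program of the transcription factor ATF4, had 4 of 36 genes higher and 0 lower, with 8 higher adjusted over the list alone. NUPR1, a small stress-induced nuclear protein, rose from 336 ± 223 to 2857 ± 1680.5 CPM (n = 3; log2 3.06, SE 0.27, adjusted p = 0.00206). WARS, a tryptophanyl-tRNA synthetase, rose from 131 ± 60.1 to 545 ± 89.3 CPM (log2 2.14, SE 0.28, adjusted p = 0.00563), and ATF5 and VLDLR rose by log2 1.62 and 2.85. VLDLR read 4.34, 0.523 and 0 CPM in control replicates 1 to 3, and its log2 change was 4.34 with a pseudocount of 0.1 and 1.63 with 5; it passed in 7 of 12 paired settings. ATF4 itself did not pass (log2 1.16, SE 0.26, adjusted p = 0.0541). The list's median was 0.49, but 0.72, −0.19 and 1.16 in replicates 1, 2 and 3. Its camera call (adjusted p = 5.07e-06 without the block, 2.41e-06 with it) was lost with an estimated correlation (adjusted p = 0.525 and 0.774). Of the 4 genes, 3, 3 and 1 passed without replicate 1, 2 and 3; the gene that passed without replicate 3 was NUPR1.

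In the list of liver X receptor targets and lipid efflux, 3 of 16 genes rose, with 6 higher and 3 lower adjusted over the list alone. The 3 were the desaturases FADS2 (log2 3.61, SE 0.39, adjusted p = 0.00314), SCD (above) and FADS1 (2.14, SE 0.36, adjusted p = 0.0177). The list was mixed, with 9 genes above 0 and 7 below, and an effect through these receptors was not tested. Camera called this list higher without the block (adjusted p = 0.0163; 0.525 with an estimated correlation) and not with it (adjusted p = 0.0548). The call held in 12 of 21 other settings; without the block it was lost with no filter (adjusted p = 0.0774), with quantile normalization (0.0567), without control replicate 3 (0.147) and without TSN replicate 1 (0.308). FADS1 did not pass without replicate 3 (log2 2.45, adjusted p = 0.0678).

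**Figure D3:**
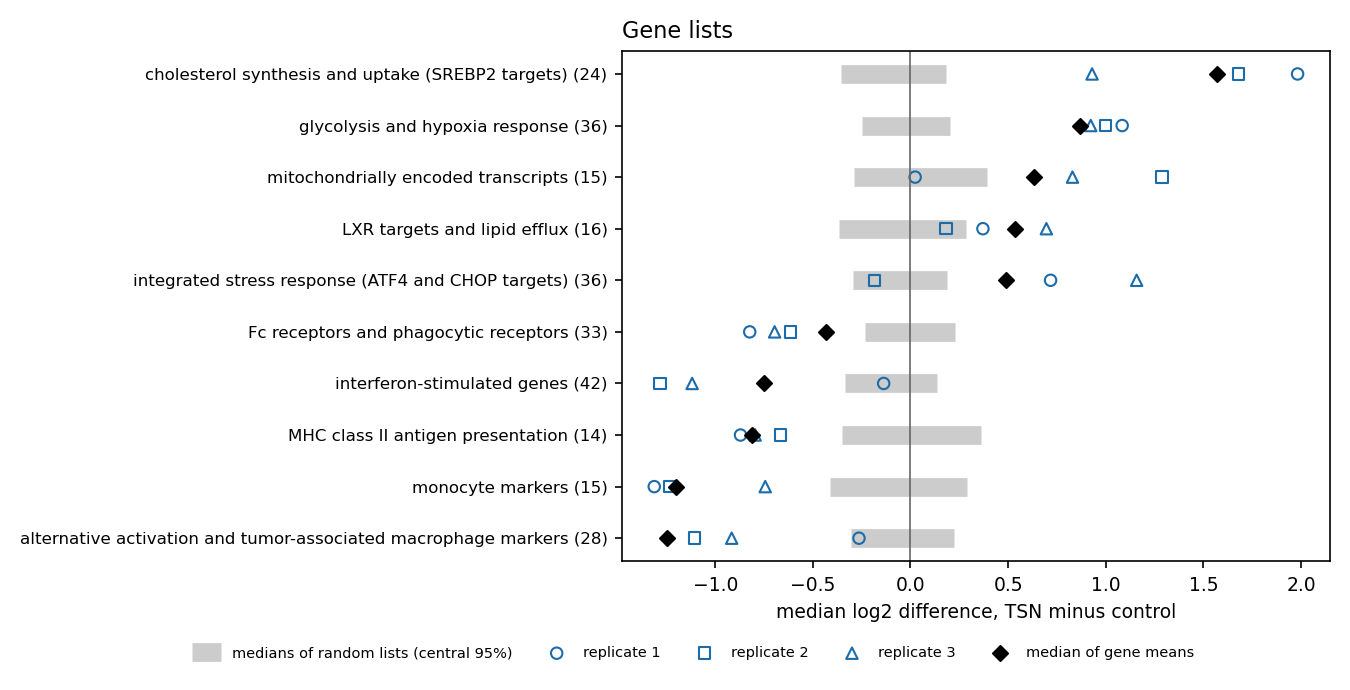
Median log2 difference (TSN minus control, horizontal axis) of the 10 lists called by camera without the block, with the number of genes tested in parentheses; diamonds are medians of gene means over the 3 pairs, open symbols are single replicates and grey bars are the central 95% of such medians of random lists matched on expression, over the mean of the pairs and not for single replicates. The diamonds of sterol synthesis (1.57) and glycolysis (0.87) lie farthest right and those of alternative activation (−1.25) and monocyte markers (−1.20) farthest left.

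Alternative activation markers were lower as a group. Of 28 tested, 9 fell, 2 rose and 17 did not pass, and adjusted over the list alone 15 fell and 3 rose. In addition to CD163, MRC1, IL10 and CCL24, CLEC10A, a lectin of alternatively activated macrophages, fell from 142 ± 156 to 27.6 ± 37.6 CPM (n = 3; log2 −2.88, SE 0.42, adjusted p = 0.00975). SPP1, encoding osteopontin (log2 2.62, SE 0.56, adjusted p = 0.0474), and CHI3L1, a chitinase-like protein (2.28, SE 0.45, adjusted p = 0.0356), rose; they were chosen after their values were seen. SPP1 did not pass without replicate 1 (log2 2.03, adjusted p = 0.0857) or 3 (2.07, adjusted p = 0.320) and passed in 6 of 14 paired settings, and CHI3L1 (1.56, adjusted p = 0.292) and CLEC10A (−2.24, adjusted p = 0.0625) did not pass without replicate 3. MARCO, a scavenger receptor, did not pass (log2 1.17, SE 0.27, adjusted p = 0.0663); it passed in 4 of 14 paired settings, among them without replicate 2 (1.34, adjusted p = 0.0433). The list's median was −1.25, against −0.30 to 0.22 for random lists, and −0.26, −1.11 and −0.92 in replicates 1, 2 and 3. The mitochondrial share with TSN was 1.12, 2.30 and 1.56 times that of the control in these replicates. Its camera call (adjusted p = 0.00301 without the block, 0.00165 with it) was lost with an estimated correlation (adjusted p = 0.227 and 0.498) and, without the block, when control replicate 2 was left out (adjusted p = 0.0526). Of the 11 genes, 8, 9 and 3 passed without replicate 1, 2 and 3.

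Receptors for antibody and for phagocytosis, and monocyte markers, were lower too. Of 33 receptor genes, 6 fell, 0 rose and 27 did not pass (15 lower and 1 higher adjusted over the list alone). They included FCGR3A, the Fc receptor CD16a, from 854 ± 318 to 257 ± 74.9 CPM (n = 3; log2 −1.71, SE 0.24, adjusted p = 0.00827) and the complement gene C1QC, from 1047 ± 717 to 348 ± 407 CPM (log2 −1.995, SE 0.31, adjusted p = 0.0143). MERTK, a receptor for apoptotic cells, fell from 189 ± 188 to 48.7 ± 67.0 CPM (log2 −2.25, SE 0.37, adjusted p = 0.0177). STAB1, a scavenger receptor, fell by 2.04 on the log2 scale. The lists overlap: MRC1, STAB1 and MERTK are also in the alternative activation list, and CD14 is in both the receptor and the monocyte list. Their falls are thus counted in more than 1 list. Of 15 monocyte markers, 4 fell and 0 rose (9 lower and 1 higher adjusted over the list alone). FCN1, a ficolin, fell from 129 ± 13.7 to 23.4 ± 14.1 CPM (log2 −2.59, SE 0.34, adjusted p = 0.00563). S100A9, a calcium-binding protein, fell from 609 ± 226 to 194 ± 107 CPM (log2 −1.77, adjusted p = 0.0119). CD14, the endotoxin co-receptor, fell from 742 ± 243 to 314 ± 56.7 CPM (log2 −1.20, adjusted p = 0.0398). The chemokine receptor gene CCR2 also fell (log2 −2.57, adjusted p = 0.0474), but it passed in only 4 of 12 paired settings, and its log2 change was −4.13 with a pseudocount of 0.1 and −1.32 with 5. The camera call of the receptors (median −0.43; adjusted p = 0.000507 without the block, 0.000161 with it) was lost with an estimated correlation (adjusted p = 0.201 and 0.498). So was that of the monocyte markers (median −1.20; adjusted p = 0.000591 and 0.000629; adjusted p = 0.166 and 0.498 with an estimated correlation). Without replicate 3, 0 of the 6 receptor genes and 0 of the 4 monocyte genes passed; 6 and 3 passed without replicate 1, and 5 and 2 without replicate 2.

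Lower values were also found in antigen presentation and interferon lists. Among 14 genes of MHC class II presentation, only HLA-DPA1 fell, from 674 ± 374 to 292 ± 188 CPM (n = 3; log2 −1.24, SE 0.24, adjusted p = 0.0315), and 7 fell adjusted over the list alone. The list's median was −0.81, and its camera call (adjusted p = 0.000591 without the block, 0.00165 with it) was lost with an estimated correlation (adjusted p = 0.166 and 0.498), without TSN replicate 1 (0.0808) and, with the block, without replicate 1 (0.0733). Among 42 interferon-stimulated genes, only SIGLEC1, a macrophage sialic acid receptor, fell, from 636 ± 605 to 135 ± 84.9 CPM (log2 −2.04, SE 0.30, adjusted p = 0.0109), and 12 fell adjusted over the list alone. That list had a median of −0.75, but −0.14, −1.28 and −1.12 in replicates 1, 2 and 3, and the mitochondrial share with TSN was 1.12, 2.30 and 1.56 times that of the control in the same order. Its camera call (adjusted p = 1.20e-06 without the block, 1.39e-05 with it) was lost with an estimated correlation (adjusted p = 0.432 and 0.774). HLA-DPA1 did not pass without replicate 2 (log2 −1.14, adjusted p = 0.0841) or 3 (−1.27, adjusted p = 0.318), nor SIGLEC1 without replicate 3 (−1.66, adjusted p = 0.166).

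Mitochondrially encoded transcripts were called higher by camera (adjusted p = 0.000167 without the block, 1.44e-05 with it; 0.525 and 0.774 with an estimated correlation), although 0 of the 15 passed and 1 was higher adjusted over the list alone. MT-RNR2, the large mitochondrial ribosomal RNA, had a log2 difference of 1.43 (SE 0.49, adjusted p = 0.183), and MT-CO1, a cytochrome oxidase subunit, 0.52 (SE 0.50, adjusted p = 0.632), which was −0.10 after quantile normalization. The list's median was 0.02, 1.29 and 0.83 in replicates 1, 2 and 3.

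The remaining lists were not called, with single members past the threshold. In the T cell inhibitory list (23 genes; camera adjusted p = 0.824 with the block), IL10 fell and PTGES, a prostaglandin E synthase, rose. Of 33 inflammatory mediators (adjusted p = 0.573), SOD2, the mitochondrial superoxide dismutase, rose from 1623 ± 253 to 4903 ± 1119 CPM (n = 3; log2 1.58, SE 0.32, adjusted p = 0.0377). Of 50 lysosomal genes (adjusted p = 0.945; median 0.01), CTSC fell by 1.99 and FUCA1 by 1.75 on the log2 scale, and CTSL fell 2.83-fold. Of 21 Src-family, Abl and associated kinases and adaptors (adjusted p = 0.395), FGR rose by 1.76, while CSF1R fell by 2.58 and DOK2 fell 3.06-fold. Of 21 STAT3 targets (adjusted p = 0.441), BCL6 rose by 1.48, while IL10, CEBPD and HIF1A fell by 3.10, 2.59 and 1.59. Of 23 matrix genes (adjusted p = 0.945), COL4A2 rose by 2.38, while TGFBI fell by 3.25 and CTSL 2.83-fold. The heme oxygenase HMOX1 fell by 1.63 among 25 NRF2 targets (adjusted p = 0.945) and ZFP36, an mRNA decay factor, by 1.82 among 23 immediate early genes (adjusted p = 0.946). OPTN, an autophagy receptor, rose by 2.37 among 33 autophagy genes (adjusted p = 0.814) and the transferrin receptor TFRC by 1.57 among 13 metal genes (adjusted p = 0.642). Without replicate 3, IL10, CSF1R and TGFBI passed and the others named in this paragraph did not. Adjusted over the list alone, the counts higher and lower were 3 and 7 in the inhibitory list, 2 and 3 among inflammatory mediators, and 1 and 4 among lysosomal genes. They were 1 and 3 among kinases, 2 and 4 among STAT3 targets, and 3 and 4 among matrix genes. They were 0 and 1 among NRF2 targets, 2 and 3 among immediate early genes, 1 and 0 among autophagy genes, and 1 and 2 among metal genes.

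In 9 other lists of cell processes, 0 genes passed and camera called none with the block. These were MHC class I (20 genes, adjusted p = 0.573), vacuolar ATPase (17, 0.573), the unfolded protein response (27, 0.225) and heat shock (19, 0.441), and also nuclear-encoded oxidative phosphorylation (74, 0.123), ribosomal proteins (79, 0.494), cell cycle (24, 0.662), p53 targets (24, 0.662) and the interleukin-4 and interleukin-13 pathway (13, 0.573). T cell attracting chemokines had 5 genes tested (0.662). Adjusted over the list alone, 1 chemokine and 1 interleukin pathway gene were higher and none of the other lists in this paragraph had a gene that passed.

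Between 1 and 9 markers of each other cell type passed the filter. Some were not low, and others were near the floor of 3 reads. PECAM1 of the endothelial list averaged 571 CPM in controls and 420 CPM with TSN. IL7R of the T cell list averaged 185 and 79.3 CPM, and CSF3R of the neutrophil list 173 and 82.1 CPM, in the same order. CSF3R is also in the monocyte list, so its level does not show that neutrophils were present. Whether PECAM1 and IL7R came from cells other than macrophages was not tested. Over all libraries, LCK of the T cell list averaged only 0.692 CPM. HBD of the erythroid list averaged 2.12 CPM and OLIG1 of the fibroblast or glial list 1.55 CPM. For NK cells 6 markers were tested (median 0.66, camera adjusted p = 0.0670 with the block), for B and plasma cells 9 (0.23, adjusted p = 0.302) and for neutrophils 6 (−0.48, adjusted p = 0.573). Of 8 dendritic cell markers (0.22, adjusted p = 0.228), IL3RA, the interleukin-3 receptor alpha chain, rose from 25.03 ± 18.9 to 118 ± 65.7 CPM (n = 3; log2 2.21, SE 0.42, adjusted p = 0.0311; 0.258 without replicate 3). T cell and endothelial lists had 3 genes past the filter each (medians 0.40 and 1.29), and platelet, erythroid and fibroblast or glial lists 1 each (1.84, 1.244 and 1.13), too few for a test. Adjusted over the list alone, 2 endothelial, 2 dendritic and 1 platelet marker were higher, and 1 T cell and 1 neutrophil marker lower.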

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

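The combinations of other settings with the replicate block, leaving out whole pairs, precision weights, length and GC correction and thinning were chosen after the data were seen. Without the block, the count of genes was 0 in the main fit and under each alternative except library weights, which gave 4607 genes (3507 at least 2-fold), but whose weights did not converge (6.55 and 6.52 for control and TSN replicate 2, at most 0.83 for the others). With the replicate block it was 227, all at least 2-fold. Paired counts, the same at 2-fold, were 79 with pseudocount 0.1, 0 with no filter (1561 at an unadjusted p under 0.05), 0 with no trend (1832) and 0 in each of 20 draws thinned to equal depth, where all 227 genes kept their direction; leaving out a pair gave 36 to 456. Without the filter 26074 genes are tested; the cause of the other losses was not tested. The other paired settings gave 229 to 299 genes. Median centring moved the median of all genes from −0.08 to 0.06 and the split of calls from 109 higher and 118 lower to 147 and 95, so directions hold relative to that shift. Of the 8 markers and kinases, 0 passed in the main fit, 4 with the replicate block and 7 with library weights. The tests planned on read counts were not run. Camera called 10 lists without the block, 0 with an estimated correlation and 0 by the directional form of fry. With the block camera called 9 lists, 0 with an estimated correlation and 0 by the directional form of fry. Leaving out a pair gave 9 to 14. Each of the 10 lists kept its direction in 21 of 21 settings. The block changed no list call but that of the liver X receptor list, which passed in 12 of the 21, with adjusted p up to 0.308.

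Of 77 genes examined singly, 69 passed in the paired fit, and these 69 kept their direction in every paired setting. Of the 69, 58, 56 and 24 still passed without replicate 1, 2 and 3. All these settings, thinning included, reuse the same values, so a kept direction is not independent support. The pseudocount moved the log2 change of 10 of the 69 by over 1.5 times, among them IL10 (−5.27 with 0.1, −1.73 with 5), IL2RA and CD38, so the ranking of the largest changes depends on it. Without the block, leaving out 1 library gave log2 differences of MT-CO1 from −0.022 (without control replicate 1) to 1.404 (without TSN replicate 1); MT-CO1 was −0.10 after quantile normalization. The cause was not tested. Depth limits genes below about 4.90 CPM, the value of 3 reads in TSN replicate 3.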

Other observations

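The genes in this paragraph were chosen after their values were seen. CSF1, which encodes the ligand of CSF1R, rose with TSN from 11.2 ± 14.8 to 61.5 ± 11.9 CPM (n = 3; log2 3.12, SE 0.54, limma adjusted p = 0.0199 in the paired fit), opposite in direction to its receptor. DCSTAMP, a gene of macrophage and osteoclast fusion, read 0.51, 7.72 and 0 CPM in control replicates 1 to 3 and 7.22, 27.6 and 33.99 CPM with TSN (log2 3.10, adjusted p = 0.0467; 4.61 with a pseudocount of 0.1 and 1.82 with 5), and was below the filter without replicate 2. Of the GIMAP family of immune GTPases, GIMAP1 fell by 2.43 and GIMAP4 by 3.10 on the log2 scale, along with GIMAP6. NCF1, an NADPH oxidase subunit, rose by log2 2.03 (adjusted p = 0.00828), and its near-identical copies NCF1B and NCF1C by 2.22 and 1.90, but reads shared among these 3 make each value uncertain. Without replicate 3, GIMAP6 passed (log2 −3.58, adjusted p = 0.0287), and CSF1 (2.58, adjusted p = 0.133), DCSTAMP (2.08, adjusted p = 0.209), GIMAP1 (−2.32, adjusted p = 0.166), GIMAP4 (−2.56, adjusted p = 0.0678) and NCF1 (1.66, adjusted p = 0.147) did not.

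Of the tests below, those on the share of macrophages and on depth as the cause of gene list differences were chosen only after the results they measure were seen. The first pattern is the 227 genes of the paired fit. Correction of each pair for transcript length and GC content kept 199 of the 221 with known values, which argues against such a bias as the cause. Lower depth of the TSN libraries of replicates 2 and 3 stays open. Of 227 genes ranked on those replicates alone, 182 (80.2%) moved the same way in replicate 1, whose depths are nearly equal, against 55.2% of all genes. That share met the 75% set in advance to exclude depth, but its exact 95% interval (74.4% to 85.2%) reaches below it. The interval takes genes as independent and the check rests on 1 pair, so the interval understates the uncertainty. Of the 4 splits that part every pair, 1 (the real one) gave as many as 227 genes and the highest other gave 0, and 4 splits are too few for a share under 0.05. Without the block the real count was 0, which all 10 splits of the 6 libraries must reach, so that comparison says nothing about chance. The highest other split gave 2048 genes, which points to a structure of the samples other than treatment: it sets the 3 deepest libraries, control replicates 1 and 2 and TSN replicate 1 (3850030 to 5984659 reads, mitochondrial share 5.37% to 8.76%), against the 3 shallowest (719514 to 2324311 reads, 13.03% to 20.3%).

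The second pattern is the higher sterol synthesis and glycolysis lists, set against lower RNA quality of the TSN libraries and against their lower depth in replicates 2 and 3. RNA quality was not measured and was judged only by the mitochondrial share, which was higher in the TSN libraries. In replicate 1 that share was nearly equal (5.37% in control, 6.03% with TSN), as was depth (control to TSN ratio 0.946), yet the sterol list had a median difference of 1.98 (random lists −0.22 to 0.21) and the glycolysis list 1.08 (random lists −0.20 to 0.16). These values, from 1 pair, argue against lower depth, and against RNA quality as judged by that share, as the whole cause of either list. The random lists were drawn as unrelated genes. With the block the estimated correlation was 0.373 for the sterol list and −0.0073 for the glycolysis list. The range of random lists is therefore too narrow for the sterol list, and another difference between the 2 cultures of this pair is not excluded. An effect of TSN on sterol and glycolytic transcription was not tested apart from these values and stays open. So do the origin of the replicates and the medium given to the controls.

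The third pattern is the lower alternative activation list. In replicate 1 its median was −0.26, just below the range of random lists (−0.22 to 0.19). The margin is narrow and comes from 1 pair, and the random lists were drawn as unrelated genes. RNA quality, judged by the mitochondrial share, and lower depth therefore stay open as causes. A lower share of macrophages in the TSN cultures stays open too. The lysosomal list had medians of −0.09, −0.03 and −0.14 against −0.26, −1.11 and −0.92, above 0.5 times the latter in all 3 replicates, but in replicate 1 by 0.045, within the spread of random lists (0.153), and its 26 higher and 24 lower members go both ways. In the same replicate the receptor, monocyte and MHC class II lists had medians of −0.82, −1.31 and −0.87. A change in macrophage state with TSN also stays open, and no test here separates it from a lower macrophage share.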
